A study of Homo sapiens with 7 samples.

How the data were processed

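ChIP-seq libraries were made from VCaP cells carrying a doxycycline-inducible hairpin against ERG. Per the labels' protocols, antibody-bound complexes were isolated from sonicated nuclei and Illumina libraries were prepared. The 7 libraries were anti-ERF with vehicle, anti-ERF with 100 ng/mL doxycycline, an input for each of these, anti-AR and anti-ERG with vehicle, and 1 input for the last pair. The series describes itself as having no biological replicates.

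The authors deposited 1 table of whole-number read counts at 25158 sites, with the position of each site, a class code of 0, 1 or 2, a location letter explained at the foot of the table, and a gene name. The genome build is hg19, per the submitters' processing notes. The aligner, the peak caller, the libraries in which the sites were called, the treatment of duplicate and multiply mapped reads, the distances that define a promoter or a distal upstream site, and the meaning of the class code are not given in the sources used here. The deposited counts are raw: each column has its own sum, from 169516 to 1856190 reads. Coordinates are printed as in the table, which does not say whether starts count from 0 or 1. Gene names are those of the table, where 21426 sites carry one of 12563 names and the 3732 intergenic sites carry none. Count columns were tied to samples by antibody and by doxycycline, reading ERG high as vehicle and ERG low as doxycycline. The names of the ERF inputs give the same reading.

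Choices in this paragraph were fixed before the data were examined. Sites with fewer than 20 reads over both anti-ERF libraries were left out (122 sites, leaving 25036). The table gives no library totals, so the doxycycline to vehicle ratio was divided by the ratio of the sums over all sites, a factor of 2.425. Each site's ratio was given an exact conditional binomial (Clopper-Pearson) 95% interval. A site was called higher or lower when its ratio was at least 2-fold and its interval excluded 1. Log2 ratios used a pseudocount of 0.5 on each count and are on the log2(count + pseudocount) scale. The interval of a median over sites is the exact binomial one from order statistics, and covers the spread over sites. With 1 library per condition no dispersion can be estimated, so edgeR's quasi-likelihood test was not run, and each call compares these libraries and not the conditions. Reads are not known to be independent molecules, so the intervals cover counting error only. The 12 gene lists were scored with 1 site per gene, the one with most reads, and the median of a list was ranked among 10000 random gene sets matched in 20 bins of reads. Genes named in the text are the 10 gene-linked sites with the highest lower bound and the 10 with the lowest upper bound of the ratio, each gene once, the 5 gene-linked sites with most reads, up to 4 members with most reads per list, and ERF and ERG. All called list members, some members whose interval excluded 1, and genes with many sites were added after their values were seen.

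The lists share members: SPDEF stands in 3 of them. Genes that also stand in another list number 2 of the 30 androgen receptor target genes, 6 of the 30 ERG fusion tumour genes, 3 of the 27 ETS genes, 2 of the 29 ERK pathway genes, 3 of the 20 luminal genes and 5 of the 23 invasion and mesenchymal genes. Basal, neuroendocrine and mesenchymal genes were listed as programmes of other cell states.

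As a background measured in the same way, the rule for calling sites was applied to the ERF inputs, and to 100 draws of Poisson counts with no difference. The 20 sites with the most AR and ERG input reads per kb served as a second reference for scaling. This reference, and its size, were chosen after the ratios of sets of 10, 20, 30, 50 and 100 such sites had been seen, so all 5 are given a bootstrap spread over sites from 10000 draws. Of these only the set of 20 was used for scaling. The calling rule was tested on simulated counts with 200 changed sites, of which those above the minimum entered a run of 24823 sites. It recovered 41 of 50 sites made 3-fold higher, 45 of 49 made 4-fold higher, 46 of 50 made 3-fold lower and 49 of 50 made 4-fold lower, none in the wrong direction, and called 1.38% of the unchanged sites. A simulated list shifted by 0.5 on the log2 scale over 12549 genes came out at percentile 100.0, and none of 40 unshifted lists lay outside the central 95%. These simulated counts varied by counting error only, and the simulated lists were larger than the smallest real ones, of 9 genes. A central 95% leaves some unshifted lists outside by definition, so this result does not show that a real list outside it differs.

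Alternatives were other scalings (none, median of ratios, TMM from edgeR 4.0.16, and the input-rich sites), no minimum or a minimum of 50 reads, pseudocounts of 1 and 5, a 1.5-fold rule, a 99% interval, other choices of site per gene, sites of class code 2 alone, and subtraction of the input. For the subtraction each input was scaled to its anti-ERF library by the reads at the input-rich sites, and negative remainders were counted as no reads. Log ratios can swing widely where few reads are left. Random gene sets stayed matched on the reads before subtraction. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.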

Results

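Chromatin immunoprecipitation with sequencing (ChIP-seq), which counts the DNA fragments that an antibody against a chromatin protein pulls down, was performed in VCaP, a human prostate cancer cell line that carries the TMPRSS2-ERG gene fusion. The cells held a hairpin against ERG that doxycycline switches on. The table of read counts names the 2 anti-ERF libraries and their inputs ERG high and ERG low, read here as vehicle and doxycycline because doxycycline induces the hairpin. An antibody against ERF, an ETS family repressor, was used in cells given 100 ng/mL doxycycline and in vehicle-treated cells, each with its own input (sonicated DNA without antibody). Antibodies against ERG, an ETS family activator, and against AR, the androgen receptor, were used in vehicle-treated cells, with 1 further input. Each of the 7 libraries stood alone in its group, so no difference below has a replicate check and no p-value is given. All intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. How far ERG itself was lowered was not measured in these libraries.

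The reads were counted at 25158 sites with a median length of 607 bp. Over these sites the anti-ERF libraries held 647453 reads with vehicle and 1570283 reads with doxycycline. The anti-ERG library held 1856190 reads and the anti-AR library held 1211200. The inputs were far lower, with 270420 reads for ERF vehicle, 198924 for ERF doxycycline and 169516 for the AR and ERG input. The median site carried 20 anti-ERF reads with vehicle, 50 with doxycycline, and 8.0 and 6.0 in the matching inputs. Total sequencing depths were not given in the sources used here.

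The first comparison asked how ERF occupancy differed once the ERG hairpin was induced. Anti-ERF reads were higher with doxycycline at almost all sites: 98.5% of the 25036 sites with at least 20 reads carried more reads than with vehicle, and only 1.28% carried fewer. Summed over all sites the reads were 2.43-fold higher (95% exact interval 2.42 to 2.43). The inputs went the other way, with a doxycycline to vehicle ratio of 0.736 (0.731 to 0.740). At the 20 sites with the most reads per kb in the AR and ERG input, of which 13 were intergenic, the summed anti-ERF ratio was 1.14, with a 95% bootstrap spread over sites of 0.991 to 1.44. These sites were not alike: single ratios ran from 0.563 to 4.67, the 13 intergenic ones summed to 0.997 and the 7 gene-linked ones to 2.37, and the intervals of 9 of the 20 included the general 2.43. The summed ratio also moved with the number of sites taken, from 1.08 for 10 sites to 1.56 for 100. Because the depths are unknown, the 2.43-fold figure mixes depth with occupancy, and the values that follow are scaled to the sum over sites unless they are called unscaled.

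**Figure D1:**
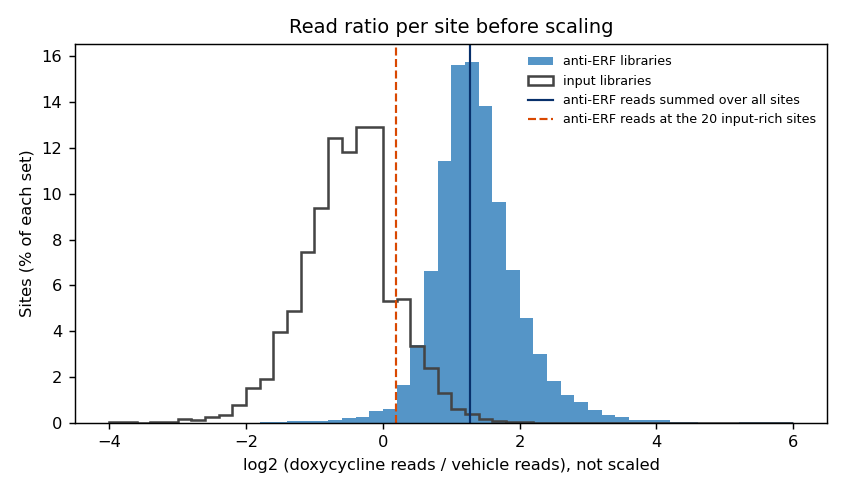
Distribution over sites of the unscaled log2 ratio of doxycycline to vehicle reads (x axis), as a percent of the sites in each set (y axis), for the anti-ERF libraries and for sites with at least 20 reads over both ERF inputs. The solid line marks the 2.43-fold ratio of summed anti-ERF reads and the dashed line the summed 1.14-fold ratio at the 20 input-rich sites, whose single ratios ran from 0.563 to 4.67.

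The gene-linked sites with the most anti-ERF reads were promoters with ratios near the general shift. They were long, from 3692 to 4365 bp, so a read total does not rank them by occupancy, and the AR site also held 380 reads in the vehicle input. The AR promoter (chromosome X, 66763387 to 66767128) had the most reads, 688 with vehicle and 1466 with doxycycline, a scaled ratio of 0.879 (0.802 to 0.963). The promoters of ING1, a chromatin reader of the p53 pathway, and ZBTB7B, a zinc finger regulator, had ratios of 0.844 (0.764 to 0.934) and 1.04 (0.939 to 1.16). IRS2, an adaptor of insulin signalling, had 1.01 (0.896 to 1.14), and E2F3, a cell cycle regulator, had 0.915 (0.802 to 1.05). The sites of AR, ING1, IRS2 and E2F3 lie in regions of raised input density, where the least raised of the 3 inputs stood at 8.35-fold (AR), 2.90-fold (ING1 and IRS2) and 2.26-fold (E2F3) of its median. The promoter of ERF itself (chromosome 19, 42757310 to 42758874) went from 55 to 137 reads, a scaled ratio of 1.03 (0.746 to 1.43), and a second ERF promoter site (42758932 to 42760177) from 36 to 65 reads, a ratio of 0.744 (0.488 to 1.15). Of the 3 sites assigned to ERG, the promoter site at chromosome 21, 40032365 to 40033415 had the highest ratio, 1.77 (0.976 to 3.42), with 14 and 60 reads, and its interval included 1. The promoter site at 39871396 to 39871835 had 0.939 (0.528 to 1.74) and the intronic site at 39984883 to 39985218 had 0.735 (0.431 to 1.28).

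Relative to the general shift, 1358 sites (5.42%) were at least 2-fold higher with doxycycline with an interval above 1, and 611 (2.44%) were at least 2-fold lower with an interval below 1. Without scaling, 18847 sites were higher and 48 lower, so the share of higher among called sites went from 69.0% to 99.75%. With the ratio at the 20 input-rich sites as the scale, 14892 were higher and 68 lower. With no difference at all, counting error alone gave 228 higher and 140 lower calls on average in 100 simulated draws. The same rule applied to the ERF inputs called 273 higher and 393 lower of 8614 sites, or 7.73%. At sites with 23 to 37 reads in the pair compared, 15.2% of the anti-ERF sites and 8.64% of the input sites were called. The libraries in which the sites were called are not given. Whether the choice of sites raised the anti-ERF share was not tested. The sites called higher had a median of 5.0 vehicle and 39 doxycycline reads, and 17.7% of them were promoters. Their median density in all inputs together was 39.8 reads per kb, against 29.4 at sites not called and 27.1 at sites called lower. The sites called lower had nearly equal medians, 24 vehicle and 23 doxycycline reads, and 28.2% of them were promoters, against 46.4% among sites not called.

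Among the 10 gene-linked sites with the highest lower bound, 8 lay in introns. An intronic site of CPVL, a carboxypeptidase (chromosome 7, 29085458 to 29085847), went from 1 to 48 reads, a scaled ratio of 19.8 (3.39 to 798). An intronic site of CDH7, a cadherin (chromosome 18, 63543602 to 63544008), went from 1 to 46 reads, a ratio of 19.0 (3.24 to 765). Intronic sites of RHOU, a Rho family GTPase (chromosome 1, 228864206 to 228864485), and ABCA12, a lipid transporter (chromosome 2, 215952079 to 215952348), had no vehicle read and 29 and 28 doxycycline reads. Set against a floor of 3 reads in the vehicle library, with the doxycycline reads taken as exact, they were at least 3.99-fold and 3.85-fold higher, and with the error of both counts the lower bounds were 3.04 and 2.93. LOC102546228 (32 reads), ZNF626 (31 reads), a site upstream of AFTPH, a clathrin trafficking gene (29 reads), and POM121C, a nuclear pore gene (28 reads), also had no vehicle read. Against the same floor they were at least 4.40-fold, 4.26-fold, 3.99-fold and 3.85-fold higher, and the lower bounds with the error of both counts were 3.37, 3.26, 3.04 and 2.93. The pseudogene CDC42P3 had 2 and 66 reads at a distal upstream site and LOC101927043 had 2 and 55 at an intronic one, ratios of 13.6 (3.62 to 115) and 11.3 (2.99 to 96.0). CDC42P3 is a pseudogene and POM121C has close copies, so counts there are uncertain, although whether the sites lie in copied sequence was not tested. The inputs held 0 to 14 reads in each library at these sites, except for 24 in the AR and ERG input at ABCA12. At none of these sites did the vehicle anti-ERF count exceed that of its own input. CPVL had 1 anti-ERF and 7 input reads with vehicle, CDH7 1 and 8, and LOC101927043 2 and 13. The large ratios thus rest on vehicle counts no higher than those of the input, though the depths are unknown.

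Among the 10 gene-linked sites with the lowest upper bound, 4 lay distal upstream of the gene and 2 at promoters. An upstream site of the non-coding gene LINC00273 (chromosome 16, 33972786 to 33973015) went from 21 reads to 1, a scaled ratio of 0.0196 (0.000475 to 0.122). An exonic site of NF1, a RAS GTPase-activating protein (chromosome 17, 29652983 to 29653223), went from 19 reads to 1, a ratio of 0.0217 (0.000522 to 0.137). At promoters, MIR3939 went from 20 reads to 2, a ratio of 0.0412 (0.00467 to 0.170), and the interferon-induced gene IFI6 (chromosome 1, 27998766 to 27999013) from 17 to 4, a ratio of 0.0970 (0.0237 to 0.297). An intronic site of CAPZA2, an actin capping gene, went from 19 reads to 4, a ratio of 0.0868 (0.0215 to 0.261). LOC101929512, MLLT10P1, TP53TG3, BAGE2 and LINC01410 had ratios between 0.103 and 0.126. MLLT10P1, TP53TG3, BAGE2 and NF1 are genes with pseudogenes or near-identical copies. Whether these sites lie in copied sequence was not tested, and the handling of multiply mapped reads is not given in the sources used here, so their counts are uncertain. Without scaling all 10 of these sites still had a ratio below 1, with the highest at 0.306 (BAGE2).

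The second comparison was by the location that the table gives each site. Promoters were the largest class, with 11127 sites and a median scaled log2 ratio of -0.038 (-0.047 to -0.029). The medians were 0.20 (0.17 to 0.22) at 3693 intergenic sites, 0.15 (0.13 to 0.17) at 5741 intronic sites and 0.065 (0.036 to 0.087) at 3208 distal upstream sites. Unscaled, the median site had 2.83-fold more reads with doxycycline at intergenic sites, 2.74-fold more at introns and 2.38-fold more at promoters. Called higher sites made up 9.72% of intergenic, 8.78% of intronic and 2.17% of promoter sites, and called lower sites 3.71%, 2.82% and 1.55%. Promoters carried more reads, with a median of 99 over both anti-ERF libraries against 51 at intergenic sites. The order turned round at the 5222 sites to which the table gives the class code 2, where the median was -0.31 at intergenic sites and -0.21 at promoters. That code goes with the ratio itself, with 5 sites called higher and 213 lower, so these sites hold few high ratios. At code 1 the medians were 0.307 at 3147 intergenic sites and 0.056 at 7800 promoters. At code 0 they were -1.8 at 94 intergenic sites and -1.39 at 76 promoters. The intergenic minus promoter difference of 0.234 was 0.924 with the input subtracted, 0.138 within bins of like reads, 0.142 with a minimum of 50 reads and 0.112 with a pseudocount of 5. The subtraction rests on the input-rich sites, which were not alike, and can leave few reads at a site.

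**Figure D2:**
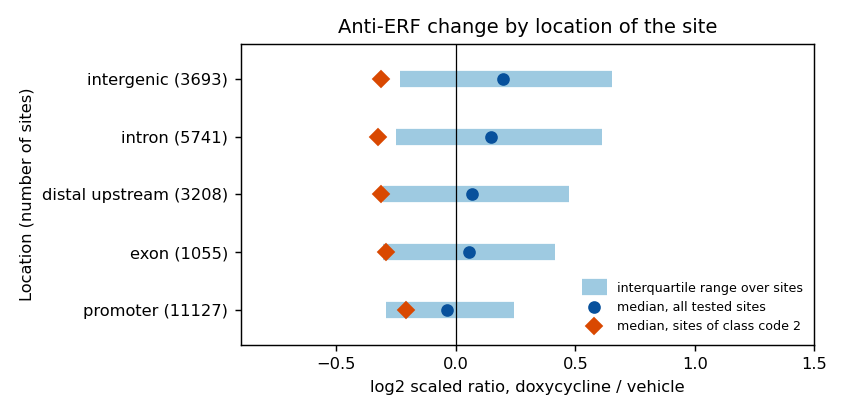
Scaled log2 ratio of doxycycline to vehicle anti-ERF reads (x axis) for the locations with at least 1000 tested sites (y axis, number of sites in brackets). Bars are interquartile ranges over sites, circles are medians of all tested sites and diamonds are medians of sites with class code 2. The circle for intergenic sites lies at 0.20 and that for promoters at -0.038, while the diamonds lie at -0.31 and -0.21.

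The third comparison was by 12 gene lists, taking for each gene the site with the most anti-ERF reads. Relative to the general shift, at most 2 members of any list were called in either direction at this site. Over all sites of the members, 6 of 41 ETS sites and 4 of 21 basal sites were called higher. Of 65 ERK pathway sites 5 were higher and 2 lower, and of 51 ERG fusion tumour sites 4 and 1. Androgen receptor targets had 4 higher of 90 sites, luminal genes 2 of 42 and splicing genes 2 of 34. The remaining lists had at most 1 in either direction. Among all tested sites 5.42% were higher and 2.44% lower. Without scaling, most members of every list but the neuroendocrine one (4 of 9) were called higher, with 21 of 23 androgen receptor target genes, 20 of 22 ETS genes, 21 of 25 ERK pathway genes and 10 of 10 invasion and mesenchymal genes. Without scaling, the sites of all members in 10 of the 12 lists had more reads with doxycycline, the exceptions being 1 ERK pathway and 1 oxidative phosphorylation gene. A list's median is set below against 10000 random gene sets of the same size matched on reads, as a description of these libraries.

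Of 23 androgen receptor target genes with a site, 1 was called higher, none lower, and the median log2 ratio was 0.038 (percentile 82.0). With the input subtracted the list stood at percentile 99.9, and with all sites of a gene at 20.5. The called gene was ACSL3, a fatty acid activating enzyme, whose promoter went from 17 to 84 reads, a scaled ratio of 2.04 (1.2 to 3.66). Its unscaled ratio of 4.94 is under 2-fold once divided by the TMM factor of 2.521, so this call depends on the scaling. TMPRSS2, the serine protease gene fused to ERG in these cells, had 16 sites and none was called, with 541 and 1381 reads in all and a ratio of 1.05 (0.952 to 1.16). NDRG1 also had 16 sites with none called, and a summed ratio of 0.836 (0.758 to 0.923). The site of KLK2, a prostate kallikrein, had a ratio of 1.07 (0.854 to 1.34), and the SPDEF promoter, of an ETS factor of prostate epithelium, had 1.17 (0.919 to 1.49).

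Of 20 genes associated with ERG fusion tumours, none was called higher and 1 lower at the site with most reads, with a median of 0.0028 (percentile 61.3). That one was the promoter of the histone deacetylase HDAC1, with 41 and 46 reads and a ratio of 0.463 (0.297 to 0.723), which turns to 1.12 (0.720 to 1.75) without scaling. CACNA1D, a calcium channel gene with 313 anti-ERG reads at its site, went from 49 to 178 anti-ERF reads, a ratio of 1.5 (1.09 to 2.10). KCNH8 and KCNS3, both potassium channel genes, had ratios of 0.861 (0.686 to 1.09) and 1.30 (0.949 to 1.80), and the LAMC2 site, of a laminin chain, had 1.07 (0.801 to 1.45). The ETS family had 22 genes with a site and a median of 0.078 (percentile 83.4). ELF4, with 7 and 41 reads, and SPIB, with 8 and 44, were called higher at 2.41 (1.07 to 6.38) and 2.27 (1.06 to 5.58). FEV, GABPA and ETS2 had ratios of 1.19, 0.991 and 1.10, all with intervals that included 1.

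The ERK pathway feedback and immediate early genes, among which ERK-regulated repressors and growth factor response genes are found, had a median of 0.087 over 25 genes (percentile 90.4). At the site with most reads only FOSB, an AP-1 subunit, was called. It was lower, with 49 and 45 reads and a ratio of 0.379 (0.247 to 0.579), or 0.918 (0.599 to 1.41) without scaling. Of the members below the 2-fold rule, SPRED2 and SPRED1, inhibitors of RAS signalling, and KLF6 had intervals above 1, with ratios of 1.4 (1.04 to 1.92), 1.54 (1.05 to 2.32) and 1.44 (1.03 to 2.05), and FOSL1, an AP-1 subunit, had one below it, at 0.641 (0.453 to 0.913). Over all 9 of its sites, however, SPRED2 had 1 called higher and a summed ratio of 0.986 (0.864 to 1.13). EGR1, JUN and SPRY2 had 0.886 (0.711 to 1.11), 1.22 (0.958 to 1.55) and 0.945 (0.712 to 1.26). No cell cycle and DNA replication gene of 17 was called (median -0.032, percentile 48.1). Among them MCM7, a replication helicase subunit, had 1.12 (0.894 to 1.41), and CCNE2, PCNA and TYMS had 1.31, 0.833 and 1.06.

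Housekeeping lists lay slightly below the general shift and within the central 95% of random sets. With the input subtracted, ribosomal and oxidative phosphorylation genes fell below it, at percentiles 0.600 and 0.880, and ribosomal genes also with all sites of a gene, at 2.03. The subtraction rests on the input-rich sites, which were not alike. All 3 lists lay above 1 without scaling (median ratios of 2.26 ribosomal, 2.25 oxidative phosphorylation and 2.29 splicing). The 36 ribosomal protein genes had a median of -0.11 (percentile 17.7) with none called, and 5 had an interval below 1, as RPL19 did at 0.527 (0.389 to 0.717), against 1 above it, RPS27. RPS19, RPS6, RPL7 and RPL15 had 0.859, 0.964, 1.04 and 0.888. The 30 oxidative phosphorylation genes had a median of -0.12 (percentile 14.9), and the complex I gene NDUFA5 was called lower at 0.394 (0.210 to 0.740), or 0.957 (0.508 to 1.80) without scaling. COX8A, NDUFV1, COX5A and ATP5G2 had 0.874, 0.928, 0.910 and 1.21. Of 25 splicing factor genes, PRPF19 was called higher at 2.11 (1.02 to 4.90), and the median was -0.097 (percentile 26.3). Without scaling PRPF19 had 5.11 (2.47 to 11.9), with a lower bound under the TMM factor of 2.521, so this call depends on the scaling. U2AF2, SF3B2, PTBP1 and HNRNPU had 0.974, 0.954, 0.956 and 1.39.

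Lineage lists gave the widest spread between medians, but the basal and neuroendocrine lists were the smallest, with 9 genes each. Medians of their random sets spanned -0.323 to 0.292 and -0.361 to 0.39, against -0.185 to 0.106 for the 36 ribosomal genes. Among 12 lists, 1 outside a central 95% can also occur by chance. Luminal prostate identity genes had a median of -0.093 over 16 genes (percentile 25.9). HOXB13, a homeobox gene of the prostate, had a ratio of 0.735 (0.580 to 0.936) and FOXA1, a pioneer factor, 1.0 (0.784 to 1.29), while the epithelial cadherin CDH1 was called higher with 6 and 35 reads (2.41, 1.0 to 7.0). The CDH1 call also depends on the scaling, since its unscaled lower bound of 2.43 lies under the TMM factor of 2.521. Basal epithelial genes had the highest median, 0.39 over 9 genes, at percentile 99.3. TP63, the basal transcription factor, was called higher on 6 and 45 reads at an intronic site, with a ratio of 3.09 (1.32 to 8.87). EGFR, the epidermal growth factor receptor, had 1.82 (1.19 to 2.87), JAG1, a Notch ligand, 1.36 (0.975 to 1.93), LAMA3 1.32 (0.889 to 2.02) and ITGA6 0.878 (0.630 to 1.24). With promoter sites alone the median of this list turned to -0.195 (percentile 18.3). Neuroendocrine genes had the lowest median, -0.36 over 9 genes (percentile 2.70, none called), although their unscaled median ratio was 1.93. The median was -0.129 (percentile 13.9) with all sites of a gene and -0.526 (percentile 0.795) with a pseudocount of 5. SRRM4, a neural splicing factor, had 0.618 (0.455 to 0.845), FOXA2 1.25 (0.849 to 1.87), SCG3 0.935 and INSM1 0.851. Of 10 invasion and mesenchymal genes, CDH2, the neural cadherin, was called higher on 3 and 30 reads (4.12, 1.28 to 21.1), and the median was 0.0010 (percentile 45.0). ITGB1, SPARC and SNAI2 had 0.946, 1.0 and 0.855.

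**Figure D3:**
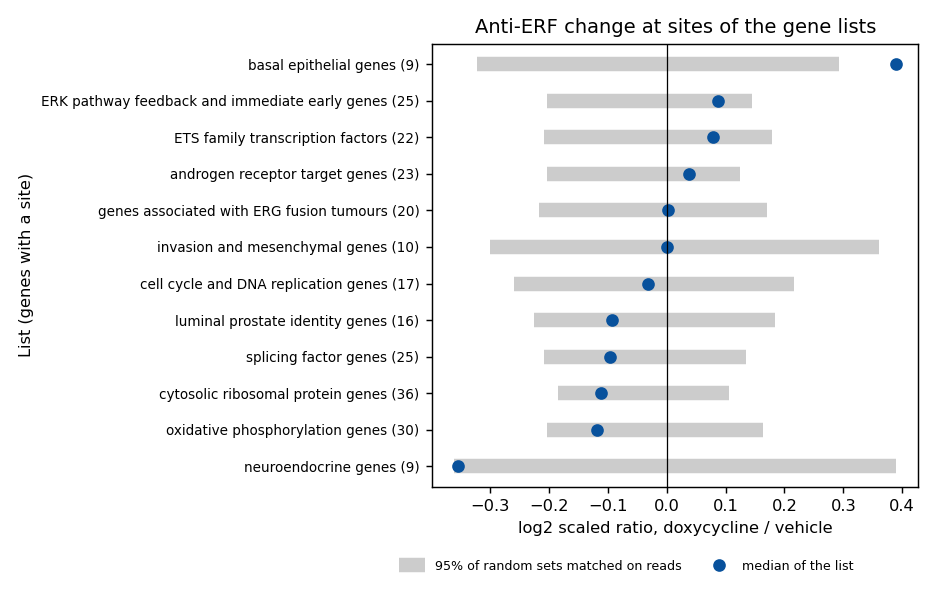
Median scaled log2 ratio of doxycycline to vehicle anti-ERF reads (x axis, circles) for 12 gene lists (y axis, number of genes with a site in brackets). Grey bars span the central 95% of medians of random gene sets matched on reads, and the basal epithelial list, at 0.39, lies outside its bar.

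The last comparison asked whether the anti-ERF difference varied with ERG or AR occupancy in vehicle-treated cells. Across all sites it barely did by terciles of read number. The median log2 ratio was 0.050, 0.017 and 0.051 in the lower, middle and upper tercile of anti-ERG reads, and 0.057, 0.030 and 0.033 in the terciles of anti-AR reads. By terciles of reads per kb the upper exceeded the lower by 0.123 for ERG and 0.107 for AR. Sites with more ERG or AR reads also had more ERF reads, with a median of 50 in the lower and 103 in the upper ERG tercile. At like ERF reads the order was clearer. Within 6 bins of anti-ERF reads the upper ERG tercile exceeded the lower by 0.072 to 0.19, and the upper AR tercile exceeded the lower by 0.017 to 0.27, on the log2 scale. Across sites, anti-ERF reads per kb with doxycycline had a Spearman correlation of 0.483 with anti-ERG and 0.471 with anti-AR reads per kb, against 0.247 and 0.233 for anti-ERF with vehicle. Its correlation with its own input was nearly as high, at 0.447, and that with anti-ERF with vehicle was 0.468. The ERF inputs correlated with each other at 0.586. The Pearson correlations of log2 reads lay closer together, at 0.532 with doxycycline and 0.429 with vehicle for ERG, and 0.643 and 0.526 for AR. Sites are not independent replicates, and the vehicle library had fewer reads.

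**Figure D4:**
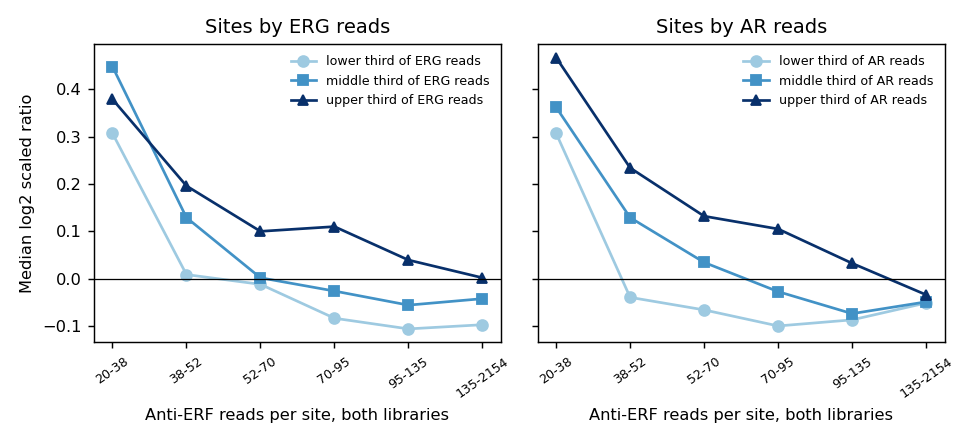
Median scaled log2 ratio of doxycycline to vehicle anti-ERF reads (y axis) in bins of the anti-ERF reads per site summed over both libraries (x axis), for terciles of anti-ERG reads (left panel) and of anti-AR reads (right panel) taken within each bin. The upper tercile lies above the lower in all 6 bins of both panels.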

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

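The input libraries, which the comparisons above do not use as a measurement, had raised read densities in 6 windows of 2 Mb with at least 20 sites each. In all of them every input had a median density at least 2 times its own median over all sites. The values below are the lowest of the 3 inputs, and these windows were looked for after the data were seen. The highest lay around the AR gene on chromosome X at 66 to 68 Mb, where the density over 31 sites was 8.35-fold that of the median site. Chromosome 13 had 2.90-fold at 110 to 112 Mb (120 sites, with IRS2 and ARHGEF7) and 2.16-fold at 112 to 114 Mb (27 sites). Chromosome 6 had 2.26-fold at 20 to 22 Mb (34 sites, with CDKAL1) and 2.12-fold at 10 to 12 Mb (25 sites, with NEDD9). Chromosome 11 had 2.12-fold at 64 to 66 Mb (155 sites, with MALAT1). The unscaled anti-ERF ratio of doxycycline to vehicle in these windows was between 2.09 (around AR) and 2.39, against 2.43 over all sites. The windows hold the sites of AR, IRS2, ING1 and E2F3, and no explanation was tested.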

How the results depend on the processing

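The scaling decides how many sites are called and most of the lower calls: with the scaling at input-rich sites all 1358 higher calls stayed higher and 68 of 611 lower calls stayed lower. That factor, 1.144, is smaller than the main one of 2.425, so it raises every ratio. No higher call could therefore be lost, and their number shows no stability. The alternatives at input-rich sites, at class code 2, with the input subtracted, matched on reads, per kb and with promoter sites were chosen after seeing the data. The number of called sites (1969, of which 1358 higher and 611 lower) became 18895 (18847 and 48) with no scaling and 14960 (14892 and 68) with the scaling at input-rich sites, which moved the median log2 ratio from 0.037 to 1.32 and 1.12 (shifts of 1.28 and 1.08). Median-of-ratios and TMM scaling gave medians of -0.023 and -0.019, with 60.8% and 61.2% of calls higher against 69.0%. A minimum of 50 reads left 844 calls (570 and 274), the 1.5-fold rule gave 3298 (1864 higher, 1434 lower), the 99% interval 1086 (616 and 470), 1 site per gene 569 (386 and 183), and class code 2 alone 218 (5 and 213). The median log2 ratio was -0.017 with the minimum of 50 reads, 0.017 and -0.13 with pseudocounts of 1 and 5, -0.24 at class code 2 and 0.13 (0.125) with the input subtracted. The intergenic minus promoter difference (0.234) was 0.142 with the minimum of 50 reads, 0.112 with the pseudocount of 5, 0.138 matched on reads, 0.924 with the input subtracted and -0.103 at class code 2. The upper minus lower ERG tercile difference (0.0014) was 0.092 with the minimum of 50 reads, 0.099 with the pseudocount of 5, 0.296 at class code 2, 0.081 with the input subtracted, 0.135 matched on reads, 0.123 per kb and 0.072 matched on AR and reads. For AR terciles (-0.024) the values were 0.060, 0.10 (0.101), 0.255, 0.052, 0.162, 0.107 and, matched on ERG and reads, 0.105, with -0.0059 for the pseudocount of 1. The number of gene lists outside the central 95% of random sets (1, the basal list) was 2 with pseudocount 1 and 2 with pseudocount 5 (basal and neuroendocrine), 2 with all sites of a gene (basal and ribosomal), 3 with the input subtracted (androgen receptor targets at 99.9, ribosomal at 0.600 and oxidative phosphorylation at 0.880, with the basal list inside), 0 with 1 promoter site per gene and 0 of the 10 lists scored with class code 2 only, where the basal and neuroendocrine lists had fewer than 3 sites and were not scored. The basal list ranged from percentile 18.3 to 99.6 over 12 settings and was outside in 10. The 10 highest and 10 lowest ranked sites kept their sign under all 4 other scalings, while the promoter of HDAC1, called lower, stood at 1.12 without scaling. A scaling shifts all sites alike, by at most 1.28 here, and the ranked sites were picked for extreme bounds, so their signs could not turn. Of the values of the main results under the alternatives, 35 stayed within the interval or 1.5 times of the main value and 54 moved. Of those of these sites and of single lists, 182 stayed within the interval of the main value and 39 moved. The basal list turned from 0.39 to -0.195 with 1 promoter site per gene, and 23 of 94 list medians changed sign under alternatives other than a scaling, which shifts all lists alike. The pseudocount is added before the scaling, so a larger one draws ratios toward equal unscaled reads, below the general shift. The pull is strongest where reads are few, so the values with larger pseudocounts follow in part from read numbers by construction. The cause of the other movements was not tested, apart from the smaller number of sites left by a minimum, a class or 1 site per gene. Subtracting the input by depth was not run because no depths are given, and the site nearest the start of a gene was not run because the table holds no distances. No paired analysis was possible because each condition has 1 library.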

Other observations

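Some genes held several sites that were called in the same direction. FHIT, a large gene at a common fragile site, had 4 of 11 sites called higher with doxycycline, and so did NTM, a neural adhesion gene (4 of 8), and ZBTB20, a zinc finger repressor (4 of 8). ASIC2 (3 of 14), GRIK4 (3 of 9), MACROD2 (3 of 16), EYS (3 of 5) and CDKAL1 (3 of 10) followed, and of these 8 genes only CDKAL1 had a site called lower, 1 of its 10. Among called lower sites, LINC00273 had 4 of 4, LOC101929512 4 of 5, LINC01410 3 of 3 and ACSS1, a mitochondrial acetyl-CoA synthetase, 3 of 6. Whether these lower sites lie in copied sequence was not tested, and the handling of multiply mapped reads is not given. No more than 1 site was called in any of the 12 genes of the fixed lists with at least 6 sites. CCND1, encoding cyclin D1, had 1 of 7 sites called lower and a summed ratio of 0.909 (0.789 to 1.05), and DUSP6, an ERK phosphatase, had none of 6 called and 0.809 (0.676 to 0.971). CACNA1D had 1 of 6 called higher and a summed ratio of 1.35 (1.10 to 1.67). These genes were picked after their values were seen.

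The class code of the table went with the ratio. The meaning of the code is not given, and if it records in which libraries a site was called, this link is circular. The 331 tested sites of code 0 had an unscaled median ratio of 0.769, with 20 vehicle and 16 doxycycline reads at the median. The 19483 of code 1 had 2.73, with 17 and 44 reads. The 5222 of code 2 had 2.07, with 42 and 88 reads, and the most ERG reads (a median of 89 against 50 for code 1 and 20 for code 0). Of the 1358 sites called higher, 1353 had code 1, and of the 611 called lower, 299 had code 0, 213 code 2 and 99 code 1.

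All tests in the next 3 paragraphs were chosen after data had been seen, and for ERG within AR terciles and for class code 2 the bounds were set before those values were computed. Anti-ERF reads were 2.43-fold higher over the sites with doxycycline. A deeper doxycycline library cannot be told apart from other causes: the 20 input-rich sites had a summed ratio of 1.14, but 9 of them had intervals that included 2.43, the 7 gene-linked ones summed to 2.37, and in a set of 100 the bootstrap spread reached 1.83. At the 20 sites the input ratio moved up, from 0.736 to 1.08, a factor of 1.47, while the anti-ERF ratio moved down by a factor of 2.12. The input departure thus goes the other way and does not account for the lower anti-ERF ratio there. A choice of sites from the doxycycline library stays open too, because the input-rich sites were not alike. The 1000 sites with most vehicle reads had a ratio of 2.12, which is 1.85 times that at the 20 input-rich sites but only at least 1.15 times with the spread of the larger sets. A more efficient immunoprecipitation and more bound ERF cannot be told apart by the 98.5% of sites with more reads, which both predict in a design of 1 library per condition. If lowering ERG opens sites to ERF, the gain may be larger where ERG was strong, and the ERG tercile difference within AR terciles was 0.0724 on the log2 scale (above 0 in 14 of 18 bins), against 0.105 for AR within ERG terciles, so that the ERG difference was not the larger one (-0.0327), and with bins from -0.155 to 0.247 this decides neither way.

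The 611 sites called lower had almost equal reads in both anti-ERF libraries. Regions rich in background reads are argued against as a general account, because the median input density of these sites was 0.924 times that of sites not called. A fixed background that the scaling pushes below 1 and a loss of ERF at these sites cannot be told apart here. With the scaling at input-rich sites 11.1% of them (68 of 611) stayed lower, but a factor near 1 ends such calls at sites with near-equal reads by construction, so that value decides nothing.

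Intergenic sites had a larger relative anti-ERF gain than promoters, by 0.234 on the log2 scale, a size that ranged from 0.112 to 0.924 with the pseudocount of 5 and with the input subtracted. Fewer reads at intergenic sites as the whole cause is argued against by the read bins, where the mean difference was 0.138 and all 6 bins were above 0 (0.016 to 0.24). The bins match the reads of both anti-ERF libraries, which also enter the ratio. They do not match site length, with a median of 871 bp at promoters and 438 bp at intergenic sites, so read density was not matched. Choice of the sites by calls in 1 library may account for it: at class code 2 the difference was -0.103 (95% bootstrap interval over sites -0.158 to -0.033). At code 1, with 77.8% of the sites, intergenic sites kept the higher median, 0.307 against 0.056 at promoters. At code 0 they had the lower one, -1.8 against -1.39. The meaning of the code is not given and the code goes with the ratio itself, so these values decide nothing and the choice of sites stays open. A difference in how ERF and ERG share distal sites also stays open and was not tested.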
